A study of Mus musculus with 69 samples.

How the data were processed

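Histone modifications were measured in blood-forming cells of mice with a conditional Kmt2c allele. Kmt2c encodes MLL3, an enzyme that places H3K4me1, the mark of enhancers, and H3K27ac marks active enhancers and promoters. Per the labels, haematopoietic stem cells (HSCs) and haematopoietic progenitor cells (HPCs) were sorted and fixed, chromatin was precipitated with an antibody against 1 of the 2 marks, and the bound chromatin was tagged with the Tn5 transposase (ChIPmentation). The genotypes were wild type, heterozygous (1 conditional allele and the Vav-Cre transgene, which is active in blood-forming cells) and knockout (both alleles conditional, with Vav-Cre). The series held 69 samples, of which 63 belonged to the 18 groups with a peak list and 6 were input chromatin, for which no list was analysed here.

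Each of the 18 groups had 1 peak list for all of its libraries, so the authors' deposited lists were pooled per group and held no separate values for the replicates. Per the submitters' processing notes, Novoalign and MACS2 were used on the build mm10 (GRCm38). Their versions, the filter applied to the lists and the way libraries were combined are not given in the sources used here. The deposited columns used here were the position of each peak, its fold enrichment (a linear ratio over background, per the authors) and its −log10 p and −log10 q as the authors' peak caller gave them. These values belong to single peaks of the authors' lists and served only to describe, rank or filter peaks within a list. The numbers in the peak names showed what the filter had left: a list kept between 46.5% and 82.0% of the ranks up to its highest, from 98.8% to 99.96% of the best 10% of ranks and from 3.88% to 46.2% of the last 10%. The lowest −log10 p in a list lay between 2.01 and 2.05. Read numbers were not used here, so the depth of the libraries is unknown.

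Peaks that overlapped or touched were merged into regions. A region was shared when it overlapped a region of the other list by at least 1 bp, exclusive when it did not, and strong when its −log10 p lay in the top 25% of its own list. For each of 17 comparisons, the share of strong exclusive regions that lay in the second list was computed with a Wilson 95% interval. The first list was the reference: wild type for genotypes, PBS for treatments and HSC for cell types. For 10 pairs of comparisons that share no list, strong exclusive regions of the first comparison that were also exclusive to 1 list of the second were counted by direction, and an odds ratio was computed with a Woolf 95% interval after adding 0.5 to each cell. These intervals cover counting error only. With 1 list per group there is no replicate error and no test between conditions, so no p-value is given, and every difference below is a difference between lists.

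For each of 21883 protein-coding genes, the bases covered by peaks between 50 kb below and 50 kb above the annotated gene were summed in each list. The log2 ratio of the covered lengths was taken after adding 1000 bases to both, and the median over all genes with at least 1000 covered bases in either list was subtracted. The result is called the relative log2 ratio, and higher, lower, more and less refer to the median gene wherever a gene list is described. Of the 45 gene lists that stood apart, 6 had a median of the opposite sign before that subtraction. For a gene list, the median of this ratio was placed among 10000 random lists of the same size matched on mean covered length in 20 bins. A list outside the central 95% of random lists, at or below percentile 2.5 or at or above percentile 97.5, is said to stand apart. A single gene was placed among the 1000 genes nearest to it in mean covered length. Members that differed from the median gene by at least 1.5-fold were counted, but no member is called changed.

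The 15 gene lists were HSC identity, granulocyte and monocyte, megakaryocyte and erythroid, lymphoid, NF-kB and IL-1 response, interferon response, antigen presentation, cell cycle, quiescence and immediate early, p53 response, H3K4 methylation and enhancer complexes, mature T, NK and B cell markers, stroma and endothelium markers, silent tissue genes and housekeeping. Of their 355 genes, 353 matched a protein-coding entry. The comparisons, gene lists, tests, alternative settings and the rule for named genes were fixed before the data were examined. The rule names 5 genes in each direction nearest to the strongest exclusive regions, up to 3 members of each list that stands apart with a difference of at least 1.5-fold in the direction of the list, and 8 reference genes, namely Kmt2c, Hlf, Mecom, Cebpa, Spi1, Il1r1, Nfkbia and Cdkn1a. Some members that the rule or a count would name are not reported here.

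The gene table used here has no strand, so the planned window around transcription start sites was replaced by the window around the gene, the nearest gene was the nearest annotated interval (the shorter gene of several), and promoters were replaced by positions within 1 kb of either annotated gene end. No genome sequence was used, so motifs were not analysed. The alternative settings were an overlap of 50% of the shorter region, peaks with −log10 q of 5 or more, lists limited to equal numbers of peaks, strength by fold enrichment, windows of 10 kb, 1 gene per 100 kb and 5000 added bases. Leaving out chromosomes X and Y, matching random lists also on window length and limiting lists to equal covered bases, by keeping the peaks with the highest −log10 p in the deposited list that together covered as many bases as the smaller list, were added after the results were seen. So were the rules that an odds ratio with an empty margin is not given and that a direction counts as reversed only where the interval of the value reported excluded equality. A recomputed value counted as the same when it lay inside the 95% interval of the value reported, or, for a count, within 1.5 times of it.

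The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The scripts were tested on simulated data made from the HSC H3K4me1 lists at 8 weeks over 21883 genes. Every region removed from 1 copy of a list was recovered, and overlaps and covered lengths equalled those of a direct search. With no difference made, 6.0% of gene lists stood apart. Both copies were random thinnings of 1 list with 80% of peaks kept, so they were alike in size and strength. The 6.0% therefore does not give the rate for deposited lists of unequal size. With 20% of the peaks around the interferon response genes removed, that list was found lower in 19 of 20 trials. These trials used the same kind of thinned copies, so they do not give the rate for deposited lists of unequal size or for smaller differences.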

Results

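H3K4me1 and H3K27ac were profiled in HSCs, which renew the blood system, and in HPCs, their more committed descendants. At 8 weeks of age, untreated wild-type, heterozygous and Kmt2c-knockout mice gave H3K4me1 lists from 3 libraries per group for both cell types. At 16 weeks, HSCs of wild-type and knockout mice were profiled after 3 doses of PBS or of 150 mg/kg 5-fluorouracil (5FU), a drug that kills dividing cells, given every 3 weeks. These H3K27ac lists came from 3 libraries each and the H3K4me1 lists from 3 to 6. HPCs of mice aged 8 to 10 weeks were profiled for H3K27ac with 4 libraries per group after 3 days of PBS or of 0.5 µg per day of interleukin-1 (IL-1), an inflammatory cytokine. The series title names chemotherapy and the activated and quiescent states of HSCs, and the comparisons ask how loss of Kmt2c, 5FU and IL-1 go with the distribution of both marks.

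The lists differed in size. The H3K4me1 lists at 8 weeks held between 111140 peaks (wild-type HPC, 102.5 Mb covered) and 134509 peaks (knockout HSC, 113.5 Mb), and wild-type HSCs had 118083 peaks over 86.1 Mb. At 16 weeks the wild-type 5FU list held 132050 peaks over 116.0 Mb, while the other 3 H3K4me1 lists held 76274 to 87410 peaks over 44.2 to 54.0 Mb. The 5FU list of the wild type drew on 6 libraries of 2 series and had 28.1% of its peaks at −log10 q of 5 or more, against 0.635%, 1.04% and 1.01% in the other 3 lists, so its difference from the PBS list holds the treatment together with the libraries. Because peak widths differed too, lists were limited either to equal numbers of peaks or to equal covered bases. Equal covered bases left unequal numbers of peaks, such as 70737 in knockout and 118083 in wild-type HSCs at 8 weeks, so neither limit removed the difference in size on both measures. Equal covered bases also took the weak peaks from the list that covered more and kept those of the other. H3K27ac lists of HSCs held 51112 to 67143 peaks and covered 33.4 to 45.4 Mb, with less covered in both knockout lists (33.4 and 36.5 Mb) than in both wild-type lists (42.2 and 45.4 Mb). H3K27ac lists of HPCs held 37002 to 41314 peaks over 36.9 to 45.9 Mb.

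Kmt2c (gene 231051, chromosome 5, 25271795 to 25498855 on mm10) was examined first. A peak list cannot show the deletion of exons, so it checks nothing about the labels. In HSCs at 8 weeks, H3K4me1 peaks covered 10024 bases around Kmt2c in the wild-type list, 19183 in the heterozygous list and 24742 in the knockout list. In HPCs the values were 6748, 5677 and 8817. In H3K27ac lists the gene had between 6658 and 7329 covered bases in all 8 groups. A second locus bore on the labels, chosen after its values were seen. In the 2 kb before the lower-coordinate end of Vav1 (chromosome 17, 57277100 to 57279100), whose regulatory sequence drives the Vav-Cre transgene, all 6 H3K4me1 lists of mice with Vav-Cre had a peak that at most 3 peaks of the same list exceeded in −log10 p, such as 57277984 to 57279108 in knockout HSCs. In the 4 wild-type H3K4me1 lists between 7.29% and 49.9% of peaks exceeded it. In H3K27ac lists the shares were 4.55% to 11.9% with Vav-Cre and 13.8% to 94.1% without it.

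HPCs differed from HSCs at the genes that define each population. In wild-type H3K4me1 lists at 8 weeks, HSC identity genes were covered less in HPCs, with a median relative log2 ratio of −0.43, lower than in all 10000 random lists. Of 29 measured members, 27 lay below the median gene and 13 were at least 1.5-fold lower. Around Tek, the angiopoietin receptor, coverage was 9993 bases in HSCs and 1874 in HPCs (−2.19), and around Mllt3, a regulator of HSC self-renewal, 77826 and 22690 (−1.99). Mecom, a transcription factor of long-term HSCs, had 109139 and 55083 bases (−1.23, percentile 0.45 among genes of like coverage).

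Genes of the descending lineages were covered more in HPCs. The granulocyte and monocyte list had a median of 0.28 (percentile 99.9, 17 of 22 members above the median gene), with Ctsg, a neutrophil protease, at 0 bases in HSCs and 3416 in HPCs, Fcgr3, an immunoglobulin receptor, at 2601 and 9601, and Ly6c2, a monocyte antigen, at 0 and 1743. Lymphoid genes had a median of 0.24 (percentile 99.3, 18 of 24 above), led by Il7r, the interleukin-7 receptor (908 and 7434 bases), Blnk, a B cell adaptor (8282 and 36104), and Dntt, which diversifies antigen receptors (9233 and 39442). Markers of mature T, NK and B cells stood apart too (0.25, percentile 98.7, 13 of 16 above), with Gzmb at 279 and 5923 bases, Ms4a1 at 0 and 3073 and Cd72 at 12917 and 27622. Cebpa, the factor that starts granulocyte differentiation, had 17689 bases in HSCs and 32612 in HPCs (0.59, percentile 96.3). These calls of the 4 lists held in every alternative, with medians of 0.18 for granulocyte and monocyte genes with 5000 added bases and 0.39 for mature cell markers with 10 kb windows. Antigen presentation genes were higher in HPCs (0.36, above all random lists, 14 of 16 above the median gene, Tapbp 0.68 and Ciita 0.61), but the percentile was 78.5 with 10 kb windows and 89.75 with 1 gene per 100 kb, and most members are neighbours. The covered bases of both lists overlapped by 49.8% of their union. Strong regions were exclusive to the HSC list in 1977 cases, led by regions in Rcbtb2, Ripor2, Thsd4 and Slc18a2 and near Ybx1, and to the HPC list in 2109 cases, led by regions in Tbrg4 (chromosome 11, 6614979 to 6617622), Galm and Sntb1 and near H60b and Gm4832. The HPC list held 51.6% of them (50.1 to 53.1), and the direction turned to 49.8% when overlaps had to cover 50% of the shorter region, to 49.3% with strength by fold enrichment and to 19.6% with lists of equal covered bases. Of regions exclusive to HPCs, 15.6% (14.2 to 17.3) lay within 1 kb of a gene end, against 7.28% (6.22 to 8.51) of those exclusive to HSCs.

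Granulocyte and monocyte genes stood apart downwards in the H3K4me1 comparison of knockout with wild-type HSCs at 8 weeks, where the median gene had a log2 ratio of 0.39. The granulocyte and monocyte list had a median relative log2 ratio of −0.21 (percentile 0.11), with 15 of 21 members below the median gene, none of them by 1.5-fold. Interferon response genes, which are transcribed in antiviral defence, had a median of −0.14 (percentile 0.37), with 21 of 28 members below. Before the median gene was subtracted both medians were above 0 (0.18 and 0.24), so the median member of both lists had more covered bases in knockout, but by less than the median gene. The granulocyte and monocyte call held in every alternative (percentile 2.13 with lists of equal covered bases), with a median of −0.12 for equal covered bases and −0.13 with 5000 added bases, and the interferon call ended with lists of equal covered bases (0.01, percentile 54.0). The list of H3K4 methylation and enhancer complexes stood apart upwards (0.16, percentile 99.8, 11 of 18 above), led by Kdm6a, the X-linked H3K27 demethylase gene that partners Kmt2c and Kmt2d (2286 bases in wild type and 8425 in knockout, 1.13), and by Kmt2c (0.83, and 0.54 with equal covered bases). With 10 kb windows its percentile was 49.5 and with equal covered bases 94.2. The share of peaks on chromosome X was 0.517% in wild-type, 0.745% in heterozygous and 0.711% in knockout HSCs, and sex is not in the labels used here. Among the reference genes, Il1r1, the IL-1 receptor, had 24065 and 23457 bases (−0.42, percentile 0.75), while for H3K27ac at 16 weeks its ratio in knockout HSCs was 0.31 (percentile 97.8) after PBS and 0.20 (92.2) after 5FU, the second 0.38 (97.35) with equal covered bases. Mecom had 109139 and 175379 (0.29, percentile 98.3, and 94.65 with equal covered bases). The relative ratios of Hlf (−0.24), Spi1 (−0.21), Cdkn1a (−0.26), Nfkbia (−0.06) and Cebpa (0.05) lay between percentiles 13.2 and 74.5. With equal covered bases Spi1 (0.06) and Nfkbia (0.10) turned and Hlf (−0.01) and Cebpa (0.31) moved, between percentiles 50.55 and 95.75.

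The knockout list of HSCs at 8 weeks held more strong exclusive regions, 1329 against 398 in wild type. That is 77.0% (Wilson 95% interval 74.9 to 78.9) in the knockout list. Its strongest lay in Zfhx3 (chromosome 8, 108737139 to 108737386), in Ehd4 (chromosome 2, 120121028 to 120123059), in Sem1 and Xrcc2 and near Gm12185. The strongest exclusive to wild type lay in Stx6 (chromosome 1, 155175003 to 155175485), Gabbr2, Lemd1, Marchf10 and Mdga2. The knockout list was also longer, with a median log2 ratio of 0.39 over all genes, and the share was 58.5% with lists of equal numbers of peaks and turned to 8.80% with lists of equal covered bases.

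Heterozygous HSCs were compared with the same wild-type list, so the knockout and heterozygous comparisons are not independent. The heterozygous list held 966 strong exclusive regions and the wild-type list 461, or 67.7% (65.2 to 70.1) in the heterozygous list, with 57.5% for lists of equal numbers of peaks and 14.4% for lists of equal covered bases. Its strongest lay in Smarca2, which encodes a chromatin remodelling ATPase (chromosome 19, 26746942 to 26747688), in Cdh23, D830031N03Rik and Cbarp and near Rasl11a. The strongest exclusive to wild type lay in Polr2f and Ddx46 and near Coro1c, Psen2 and Cmtm7. Of the regions exclusive to knockout against wild type, 77.3% (74.9 to 79.4) were covered in the heterozygous list, as were 70.1% (65.4 to 74.4) of those exclusive to wild type. With the 3 lists limited to equal numbers of peaks these shares were 76.4% (73.3 to 79.1) and 72.0% (68.2 to 75.4). As deposited, the heterozygous list covered 98.8% of strong wild-type regions shared with knockout and 98.7% of strong knockout regions shared with wild type. Kdm6a (1.12) and Kmt2c (0.63) again led the complex genes (0.14, percentile 99.8), whose percentile was 95.7 with 10 kb windows and 92.9 with equal covered bases. Silent tissue genes, a control list, stood apart at −0.12 (percentile 2.02), a call that 4 alternatives ended, with percentiles up to 15.8, while its median was −0.30 with equal covered bases, and 0.12 in the deposited lists before the median gene was subtracted. Interferon genes (−0.04, percentile 21.2) and granulocyte and monocyte genes (percentile 34.6) did not stand apart, and the difference from the knockout was not tested.

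In HPCs at 8 weeks, knockout and wild-type H3K4me1 lists had nearly equal numbers of strong exclusive regions. There were 501 in knockout and 479 in wild type (51.1%, 48.0 to 54.2), and the direction turned with lists of equal numbers of peaks (43.3%), with lists of equal covered bases (48.8%) and with −log10 q of 5 or more (23.9%). Interferon response genes stood apart downwards in knockout HPCs as well (−0.10 relative to the median gene, which had −0.01, percentile 0.25, 19 of 28 members below the median gene), in every alternative. Granulocyte and monocyte genes, lower relative to the median gene in knockout HSCs, had percentile 95.1 here and stood apart upwards (98.6) when random lists were matched on window length. Cell cycle genes stood apart upwards (0.10, percentile 98.6, 17 of 29 above), led by Mcm4, a subunit of the replicative helicase, at 950 bases in wild type and 2139 in knockout (0.69). The percentile was 94.2 with 5000 added bases and 96.5 with 10 kb windows. H3K4 complex genes had a median of 0.11 (percentile 98.2, 10 of 18 above, 95.4 when random lists were matched on window length). Antigen presentation genes had −0.07 (percentile 2.18, 13 of 16 below, a call that 5 alternatives ended, with percentiles from 3.80 to 17.2). The strongest regions exclusive to knockout lay in Tnrc18, Derl1 and Hmox2, near Ppp1r13b and 822 bp from Jak2, the kinase of cytokine receptors (chromosome 19, 29250046 to 29250981). Those exclusive to wild type lay in Pax7 (chromosome 4, 139812997 to 139814662), Ergic1, Ripor2 and Ncoa2 and near Pde4d. Regions exclusive to wild-type HPCs lay within 1 kb of a gene end in 28.6% of cases (24.7 to 32.8), against 10.2% (7.83 to 13.1) of those exclusive to knockout and 19.0% of strong wild-type regions shared with knockout. The reference genes lay between percentile 5.35 (Cdkn1a, −0.16) and 92.6 (Kmt2c, 0.35).

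Heterozygous HPCs had 436 strong exclusive regions and wild-type HPCs 399 in that comparison (52.2%, 48.8 to 55.6), which turned to 41.7% with lists of equal numbers of peaks. No gene list stood apart, and the interferon list had percentile 59.3. The strongest heterozygous regions lay in Hmox2, Rsbn1l and Nck2 and near Cfap161 and Urb2, and the strongest wild-type regions in Ndufa4l2, Tfcp2l1, Cbll1 and Tcp11l1 and near Cyren. The same wild-type list entered both HPC comparisons, and of the regions exclusive to wild type against heterozygous HPCs 23.1% (19.2 to 27.4) lay within 1 kb of a gene end, against 11.7% (9.01 to 15.1) of the heterozygous ones. The heterozygous list covered 77.6% (73.8 to 81.1) of the regions exclusive to knockout and 72.0% (67.8 to 75.9) of those exclusive to wild type, or 74.8% (70.5 to 78.6) and 72.7% (69.0 to 76.2) with the 3 lists limited to equal numbers of peaks. As deposited, it covered 99.0% of strong wild-type regions shared with knockout and 99.2% of strong knockout regions shared with wild type.

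**Figure D1:**
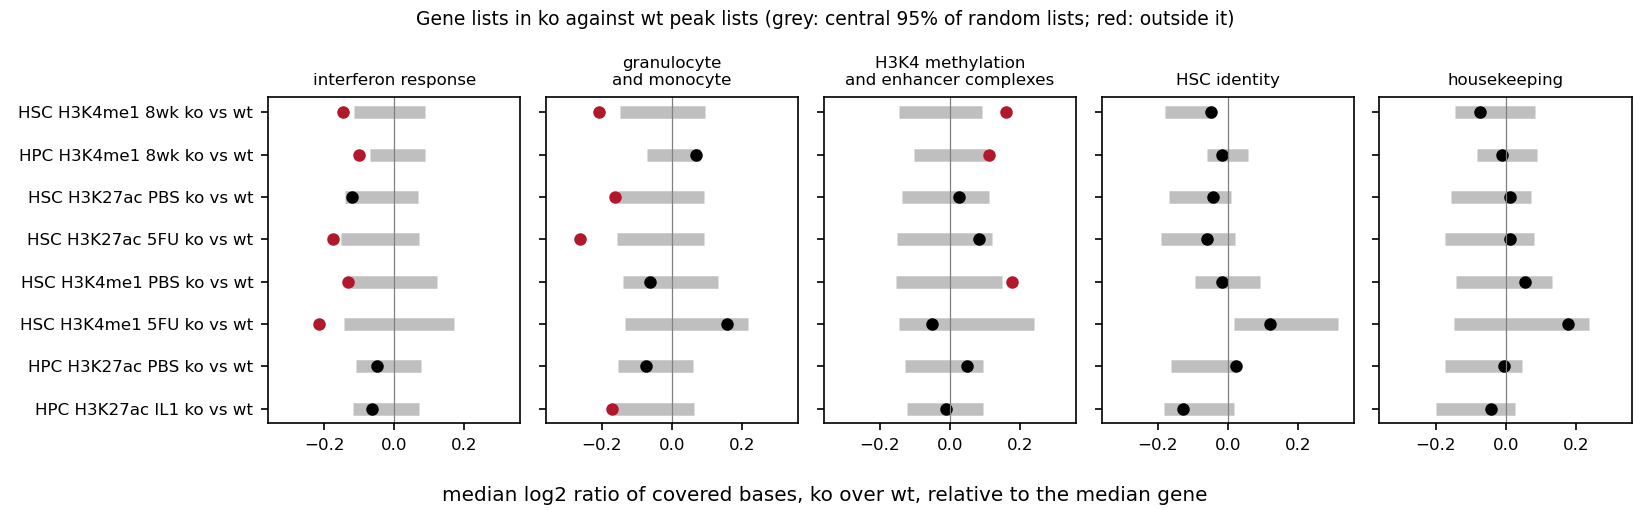
Median relative log2 ratio of covered bases, knockout (ko) over wild type (wt), for 5 gene lists (panels) in the 8 comparisons of knockout with wild type (vertical axis). Each point is 1 gene list, the grey bar is the central 95% of 10000 random lists and red points lie outside it, and interferon response genes lie below 0 in all 8 comparisons and below the bar in 5.

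H3K27ac peaks in HSCs at 16 weeks covered less around granulocyte and monocyte genes in the knockout lists after PBS and after 5FU, in calls that depended on list size. After PBS the list had a median of −0.16 (percentile 1.98, 16 of 20 members below the median gene). Around Clec7a, the beta-glucan receptor of phagocytes, coverage was 11602 bases in wild type and 5540 in knockout (−0.79), and around Itgam, the integrin CD11b, 9127 and 4788 (−0.65). After 5FU the median was −0.26 (percentile 0.13, 15 of 20 below). Csf2rb, the shared receptor chain for GM-CSF, IL-3 and IL-5, had 7766 and 1430 bases (−1.69), Cebpe, a factor of late granulocyte differentiation, 9238 and 3684 (−0.97), and Gfi1, a repressor needed for neutrophils, 3503 and 1412 (−0.74). Both calls ended with lists of equal covered bases, where the median after PBS was 0.04 (percentile 79.2) and after 5FU −0.05 (17.7). That after PBS also ended with 10 kb windows (3.61) and with 5000 added bases (3.19). In H3K4me1 lists of HSCs at the same age the list did not stand apart after PBS (percentile 18.7) or 5FU (88.5), but with 10 kb windows it stood apart downwards after PBS (−0.23, 0.615) and upwards after 5FU (0.25, 98.5).

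Cdkn1a, which encodes the cell cycle inhibitor p21 (gene 12575, chromosome 17, 29090979 to 29100722), had less H3K27ac coverage in knockout HSCs. It had 15344 bases in wild type and 7136 in knockout after PBS (−0.85, percentile 1.05 among genes of like coverage), and 15551 and 7446 after 5FU (−0.81, percentile 2.05). With lists of equal covered bases the ratios were −0.27 (percentile 11.95) and −0.26 (13.4), and that for H3K4me1 after PBS was −0.08 (8869 and 8838 bases, percentile 41.75). Its relative ratio was below 0 in all 8 comparisons of knockout with wild type, at −0.43 and −0.47 for H3K4me1 in HSCs after PBS and 5FU and at −0.41 and −0.31 for H3K27ac in HPCs after PBS and IL-1. The percentiles of the other 6 values lay between 5.05 and 26.0. The p53 response list as a whole, to which Cdkn1a belongs, stood apart in 0 of the 8, with its lowest percentile just inside the band (2.505, HSC H3K4me1 at 8 weeks).

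**Figure D2:**
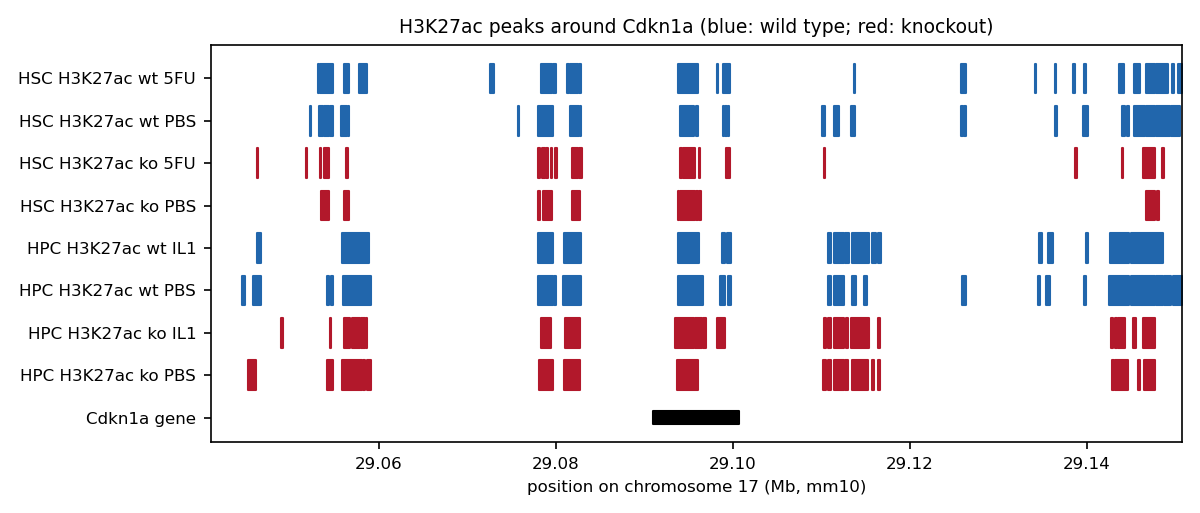
Position of H3K27ac peaks on chromosome 17 (Mb, mm10) within 50 kb of Cdkn1a in the 8 H3K27ac lists (vertical axis), with wild type (wt) in blue, knockout (ko) in red and the gene in black. Bars are peaks as deposited, and those of the HSC lists cover 15551 and 15344 bases in wild type and 7446 and 7136 in knockout after 5FU and PBS.

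Megakaryocyte and erythroid genes were also covered less by H3K27ac in knockout HSCs after PBS (−0.20, percentile 0.59, 13 of 19 members below the median gene). Itgb3, the platelet fibrinogen receptor chain, had 5905 bases in wild type and 888 in knockout (−1.72), and the platelet glycoprotein genes Gp9 and Gp5 had 19335 and 9541 (−0.79) and 2765 and 1100 (−0.69). The percentile was 5.54 with 10 kb windows and 83.7 with equal covered bases, and after 5FU the list did not stand apart. Mature T, NK and B cell markers were lower after PBS (−0.24, percentile 0.735, Cd22 6534 and 2107 bases), a call that 4 alternatives ended, with percentiles from 3.74 to 43.9. After 5FU, interferon response genes were covered less (−0.17, percentile 1.01, 20 of 28 below), with Usp18, a protease that limits interferon signalling, at 4105 and 1480 bases (−0.88). That call ended with 1 gene per 100 kb (percentile 10.7) and with 5000 added bases (2.57). After PBS the same list had percentile 4.58, and 1.01 with equal covered bases. Stroma and endothelium markers were lower after 5FU (−0.20, percentile 1.90, Col1a2 −0.63 and Kdr −0.60), and silent tissue genes, with 9 measured members, were higher (0.24, percentile 98.7). Alternatives ended both calls, with percentiles of 7.67 and 74.98.

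The strong exclusive H3K27ac regions of HSCs differed in direction between PBS and 5FU, a difference that was not tested. After PBS, 136 were exclusive to wild type and 45 to knockout, or 24.9% (19.1 to 31.6) in knockout, and the share was 45.5% with lists of equal numbers of peaks, 98.2% with lists of equal covered bases and 53.8% of 13 regions with −log10 q of 5 or more. After 5FU, 217 were exclusive to wild type and 274 to knockout (55.8%, 51.4 to 60.1), which turned to 39.9% with strength by fold enrichment and to 14.8% of 27 regions with −log10 q of 5 or more, and was 99.8% with lists of equal covered bases. After PBS the strongest wild-type regions lay in the Y-linked genes Uty (Y, 1244860 to 1246184) and Ddx3y and in Ssh1 and near Pink1 and Gna13, and the strongest knockout regions near Mid1 and Vav1 and in Epb41l4a, Zfp935 and Kcnip1. After 5FU they lay in Pik3c3, Pde3b, Rab1b and Fyb and near LOC115488016 in wild type and in Them7, Zfp407 and Rimkla and near Mid1 and Pecam1 in knockout. Mid1 lies at the boundary of the pseudoautosomal region of chromosome X. Sex is not in the labels used here, and the HSC H3K27ac lists held 2 (wild type, PBS), 3 (wild type, 5FU), 1 (knockout, PBS) and 5 (knockout, 5FU) Y-linked peaks, with a best −log10 p of 33.7, 33.5, 2.55 and 20.3.

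H3K4me1 peaks in HSCs at 16 weeks covered less around interferon response genes in the knockout lists under both treatments. The median after 5FU depended on the bases covered by the lists, and that after PBS hardly did. The list had a median of −0.13 after PBS (percentile 1.72, 17 of 27 members below the median gene). Gbp2, an interferon-induced GTPase, was the only member at least 1.5-fold lower, at 1934 bases in wild type and 570 in knockout (−0.73). Isg15 (1.25) and Stat2 (0.65) were the 2 members at least 1.5-fold higher. After 5FU the list had −0.22 (percentile 0.22, 17 of 28 below). Both calls ended with 10 kb windows (percentiles 21.9 and 23.7) and with lists of equal covered bases (4.16 and 67.4), and that after PBS also with 1 gene per 100 kb (4.63). The median after PBS was −0.131 in the deposited lists, −0.125 with equal covered bases and −0.124 with 1 gene per 100 kb, but −0.054 with 10 kb windows. After 5FU the median was 0.007 with equal covered bases and −0.079 with 10 kb windows. The H3K4 complex list stood apart upwards after PBS (0.18, percentile 99.1), 0.00 before the median gene was subtracted, led by Kmt2c (2826 and 4534 bases, 0.71) and Ncoa6, a subunit of the Kmt2c and Kmt2d complexes (5265 and 7323, 0.59), with percentile 94.5 for lists of equal numbers of peaks. After 5FU, Kmt2c went the other way, with 25285 bases in wild type and 4454 in knockout (−1.07, percentile 0.25), but 1602 and 4454 (1.00, percentile 88.95) with lists of equal covered bases. After 5FU, silent tissue genes were higher relative to the median gene (0.32, and −0.88 before it was subtracted, percentile 99.96), in a comparison whose all-gene median was −1.202. Of 14 measured members, 2 were at least 1.5-fold higher and 2 at least 1.5-fold lower. The higher ones had fewer bases in knockout, Umod 1282 in wild type and 881 in knockout (0.92) and Fgb 1383 and 766 (0.77). The list had percentiles of 45.6 with equal covered bases and 94.8 with 10 kb windows.

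After PBS, 2363 strong H3K4me1 regions were exclusive to wild type and 1416 to knockout (37.5%, 35.9 to 39.0, turned to 78.8% with lists of equal covered bases). The strongest lay in Cubn, Urgcp, H2-DMa, Pdcd1lg2 and Slc16a12 in wild type, and in Vav1, Dpp9, Ezr and Glg1 and near Hbb-bt in knockout. Of the 2 genotypes compared only the knockout carries Vav-Cre, and a peak at Vav1 (57279457 to 57280318 here) does not separate the gene from transgene sequence, which also holds for the Vav1 regions named for H3K27ac after PBS and for H3K4me1 after 5FU. After 5FU, 4796 were exclusive to wild type and 26 to knockout (0.539%, 0.368 to 0.789), and the share in knockout was 19.5% with lists of equal numbers of peaks and turned to 99.2% with lists of equal covered bases. The strongest in wild type lay in Cacna1d, Mkrn1 and Fgf12 and near Osbpl8 and Rap2a, and in knockout in Cdc42bpb, Aunip and Foxk1 and near Inf2 and Vav1. The wild-type 5FU list covered 116.0 Mb and the knockout 5FU list 44.2 Mb, so these numbers carry the difference in list size described above.

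5FU went with more H3K27ac coverage around HSC identity genes in both genotypes, though not independently of list size. In wild type the list had a median of 0.10 (percentile 98.8, 23 of 29 members above the median gene, none by 1.5-fold), and in knockout 0.12 (percentile 99.4, 21 of 29 above), led by Tek (1301 bases after PBS and 3548 after 5FU, 0.93) and Angpt1, the ligand of Tek (13610 and 25681, 0.82). Both calls ended with lists of equal numbers of peaks (93.4 and 93.1), with equal covered bases (49.0 and 91.7) and with 10 kb windows (95.2 and 82.0). For H3K4me1 the list stood apart in knockout HSCs in every alternative (0.13, percentile 99.8, 20 of 29 above) but in wild-type HSCs in none and not in the deposited lists (−0.07, percentile 88.9, 12 of 29 above). Antigen presentation genes were higher there too (0.22, percentile 99.99, 15 of 16 above, H2-Ab1 0.59, percentile 83.4 with 1 gene per 100 kb). In knockout H3K27ac lists, interferon genes were higher after 5FU (0.10, percentile 98.3, 18 of 28 above) and stroma and endothelium markers lower (−0.13, percentile 1.13), and alternatives ended both calls, with percentiles of 87.6 and 62.6.

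Strong exclusive H3K27ac regions lay mostly in the 5FU lists, with 144 against 25 in wild type (85.2%, 79.1 to 89.8) and 614 against 32 in knockout (95.05%, 93.1 to 96.5). With lists of equal numbers of peaks the shares were 57.8% and 62.4%, with equal covered bases 30.0% and 61.2%, and in knockout the direction turned to 11.1% of 9 regions with −log10 q of 5 or more. In wild type the strongest lay in Wiz, Rab1b and Pdpr and near Mid1 and Sufu after 5FU, and in Desi2, Nhsl2, Gm51877 and Hspb8 and near Mlf2 after PBS. In knockout they lay in Uty and Ddx3y and near Mid1, Hjv and Snx7 after 5FU, and in Dnajc6, Nipal2, Nhej1 and Lrrn4 and 789 bp from Bcl6, a transcriptional repressor, after PBS. For H3K4me1 in wild type, 3210 strong regions were exclusive to the 5FU list and 71 to the PBS list (97.8%, 97.3 to 98.3, with 64.5% for lists of equal numbers of peaks and 0.615% for lists of equal covered bases). In knockout, 1283 were exclusive to 5FU and 2121 to PBS (37.7%, 36.1 to 39.3), the strongest of the PBS list in Phf21b, Nfix, Aco1 and Nfib and near Ptpn7 and of the 5FU list in Emilin1, Ilrun, Ksr1, Babam2 and Ndufa12. In wild-type H3K4me1 lists, lymphoid genes were lower relative to the median gene after 5FU (−0.18, percentile 0.58, and 0.83 before it was subtracted) and H3K4 complex genes higher (0.19, percentile 99.3, Kmt2c 1.76 and Kdm6a 0.65), calls that 5 and 4 alternatives ended. Kmt2c turned to −0.30 with lists of equal covered bases (2826 and 2107 bases, percentile 42.55). Chromosome X, which carries Kdm6a, held 0.148% of peaks in the PBS list and 0.523% in the 5FU list.

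IL-1 in HPCs went with less H3K27ac around HSC identity genes. In knockout the list had a median of −0.16 (percentile 0.01, 21 of 28 members below the median gene, 3.49 with equal covered bases), led by Mllt3 (3575 bases after PBS and 529 after IL-1, −1.41) and Angpt1 (18066 and 9176, −0.73). In wild type it had −0.08 (percentile 1.37, 18 of 28 below), led by Esam, an adhesion molecule of HSCs and endothelium (12969 and 7878, −0.64), and the percentile was 3.41 with equal numbers of peaks, 6.34 with 5000 added bases and 14.5 with equal covered bases. The NF-kB and IL-1 response list, which holds targets of the pathway downstream of the IL-1 receptor, did not stand apart in wild type (percentile 93.8) or knockout (59.3). Nfkbia, the NF-kB inhibitor induced by the pathway, had relative ratios of 0.20 (percentile 89.6) in wild type and −0.03 (49.9) in knockout, the second 0.04 with equal covered bases. Quiescence and immediate early genes were higher relative to the median gene after IL-1 in knockout (0.12, and −0.05 before it was subtracted, percentile 99.9, 14 of 23 above, 89.9 with equal covered bases), led by Foxo1 (828 and 1865 bases, 0.82) and Klf2 (9496 and 14445, 0.73), both factors of resting cells. Antigen presentation genes were lower in wild type (−0.10, percentile 1.81) and knockout (−0.32, below all random lists), mostly neighbours on chromosome 17. With 1 gene per 100 kb the percentiles were 16.8 and 19.2, and in wild type 22.4 with 10 kb windows, while the knockout median was −0.18 with equal covered bases and −0.19 with 10 kb windows. In wild type, interferon genes (−0.12, percentile 0.295, Zbp1 −0.68), mature T, NK and B cell markers (−0.16, percentile 0.31) and stroma and endothelium markers (−0.12, percentile 2.41) were lower, with alternatives reaching 18.5, 7.62 and 6.05. The stroma list was lower in knockout too (−0.14, percentile 2.04, Col1a1 −0.61, up to 28.5).

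H3K27ac lists of HPCs shared nearly all strong regions. Exclusive to the IL-1 list were 6 in wild type, near Mid1, Wfdc21 and Clpx and in Slc7a5 and Dus2 for the first 5 genes, and 6 in knockout, in Auh, Rftn1 and Fndc7 and near Mid1 and Rdm1. Exclusive to PBS were 4 in wild type, in Uty, Ddx3y, Cmc1 and H2-Q6, and 0 in knockout. The Wilson interval of the share in the IL-1 list was 31.3% to 83.2% in wild type and had a lower bound of 61.0% in knockout. Between genotypes, 3 regions were exclusive to wild type after PBS, in Uty and Ddx3y and near Hsf2bp, and 0 to knockout (0% in knockout, upper bound 56.1%). After IL-1, 2 were exclusive to wild type, in P2ry10 and in Prdm16, a regulator of HSC maintenance, and 2 to knockout, near Marveld2 and in Ctbp2 (Wilson interval 15.0% to 85.0%). By gene lists, granulocyte and monocyte genes were covered less in knockout HPCs after IL-1 (−0.17, percentile 2.00, 16 of 21 below, 82.1 with equal covered bases), with Ms4a3, a marker of granulocyte and monocyte progenitors, at 4510 and 916 bases (−1.43). After PBS the list had percentile 21.7. Cell cycle genes were higher in knockout HPCs after PBS (0.12, percentile 99.9, 18 of 29 above, none by 1.5-fold) in every alternative, and antigen presentation genes too (0.06, percentile 99.9), with percentile 67.2 for 1 gene per 100 kb.

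**Figure D3:**
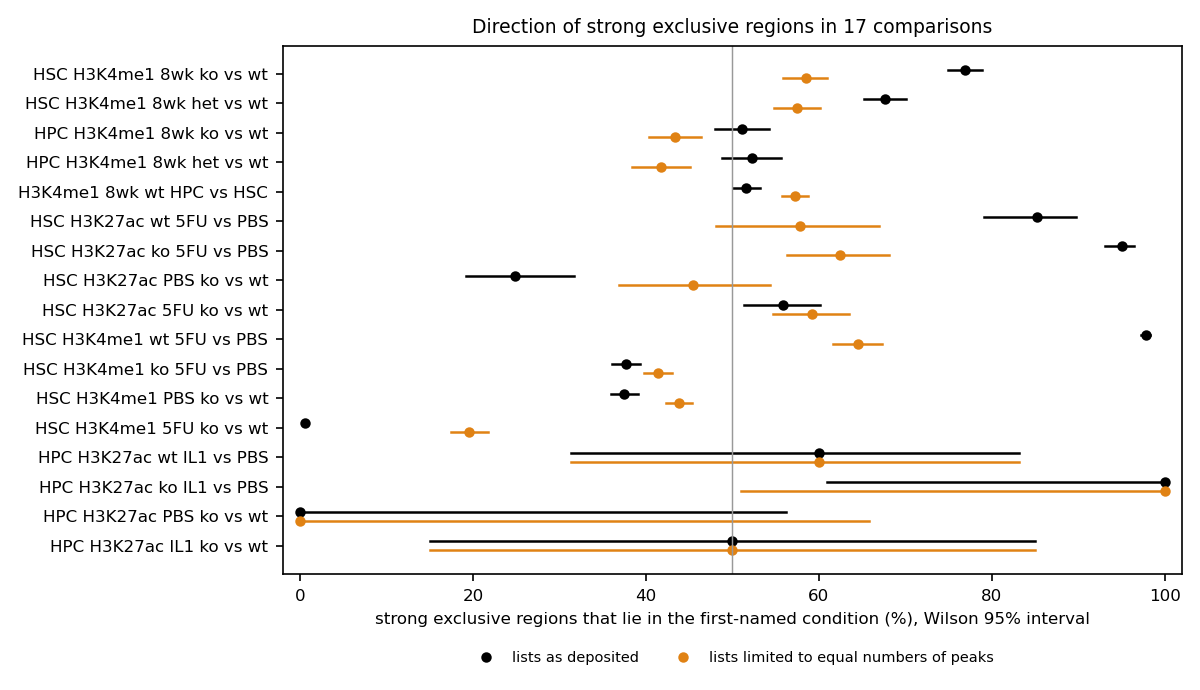
Percent of strong exclusive regions that lie in the first-named condition of each of 17 comparisons (vertical axis), with wt, het and ko for wild type, heterozygous and knockout. Points are shares, lines are Wilson 95% intervals (counting error only), black is for the deposited lists and orange for lists limited to equal numbers of peaks, and the knockout share in HSC H3K4me1 at 8 weeks is 77.0% in black and 58.5% in orange.

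Directions were then followed between comparisons that share no list. Between 8-week HSCs and HPCs the odds ratio for the same direction was 2.42 (Woolf 95% interval 1.52 to 3.87, 418 regions). Of 1329 regions exclusive to knockout HSCs, 665 lay in both HPC lists and 343 in neither. Of those in exactly 1 HPC list, 186 were on the knockout side and 135 on the wild-type side (57.9% knockout). Of 398 regions exclusive to wild-type HSCs, 191 lay in both and 110 in neither, and the others were 35 and 62 (36.1% knockout). Between HSCs at 8 weeks and HSCs at 16 weeks after PBS the odds ratio was 1.83 (1.197 to 2.81, 502 regions). Of the same 1329 regions, 341 lay in both PBS lists and 608 in neither, and 47.4% of the others were on the knockout side. Of the same 398 regions, 54 lay in both and 222 in neither, and 32.8% of the others were on the knockout side. The second ratio turned to 0.6 over 7 regions with −log10 q of 5 or more, and its interval included 1 with lists of equal covered bases (1.46, 0.840 to 2.54). For H3K27ac in HSCs, knockout against wild type after PBS and after 5FU gave an odds ratio of 51.8 (5.97 to 449.7, 31 regions). Of 45 regions exclusive to knockout after PBS, 29 lay in both 5FU lists and 5 in neither, and of 136 exclusive to wild type 114 and 2. Most of these regions were thus called in both genotypes after 5FU. Among those in exactly 1 of the 5FU lists, 10 of 11 exclusive to knockout and 18 of 20 exclusive to wild type went the same way. Without chromosomes X and Y, 4 of 5 and 18 of 19 did (odds ratio 37.0, 3.08 to 444.8). The ratio was 16.3 (3.81 to 69.3) with an overlap of 50%, 32.7 (4.83 to 221.2) with strength by fold enrichment and 27 with −log10 q of 5 or more, where the interval included 1 (0.354 to 2058, 5 regions). With lists of equal covered bases this pair gave no ratio. For H3K4me1 after PBS and 5FU it was 2.86 (1.25 to 6.54, 1383 regions). Of regions exclusive to knockout after PBS, 17 lay in the knockout 5FU list alone and 568 in the wild-type one alone (2.91% knockout). For regions exclusive to wild type after PBS these numbers were 8 and 790 (1.00% knockout). Nearly all regions in exactly 1 of the 5FU lists thus lay on the side of the larger wild-type 5FU list. For either direction after PBS, more regions lay in both 5FU lists than in exactly 1 of them. The ratio was 1.73 (1.28 to 2.36) with lists of equal covered bases. Intervals that included 1 belonged to the marks compared after PBS (4.02, 0.714 to 22.6), to HSCs against HPCs for H3K27ac after PBS (4.20, 0.680 to 26.0), and to 5FU in wild type against knockout for H3K27ac (2.94, 0.517 to 16.8) and H3K4me1 (2.18, 0.954 to 4.99). Some alternatives excluded 1. For HSCs against HPCs these were equal numbers of peaks (10.5, 1.204 to 92.0), fold enrichment (6.31, 1.14 to 34.9), an overlap of 50% (4.56, 1.01 to 20.7) and equal covered bases (12.3, 1.1 to 138.3). For 5FU they were equal numbers of peaks for H3K27ac (7.36, 1.54 to 35.2) and fold enrichment for H3K4me1 (3.24, 1.11 to 9.47). With an overlap of 50% the ratio of 5FU for H3K27ac was 1.15 (0.306 to 4.35). The remaining 2 of 10 pairs, in HPC H3K27ac lists, had 4 and 2 regions and gave no ratio.

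Over all 17 comparisons, 255 gene list medians were examined and 45 stood apart, 20 upwards and 25 downwards, where 12.75 would by the definition of the band. Silent tissue genes, a control list, were among the 45, in 2 of the 8 comparisons of knockout with wild type and in heterozygous HSCs. The excess over 12.75 is therefore not in itself evidence for the other lists. With lists of equal covered bases 32 stood apart, 20 of the 45 among them. In the 8 comparisons of knockout with wild type, interferon response genes had a relative median below 0 in 8 and below the band in 5, and granulocyte and monocyte genes in 6 and 4. Megakaryocyte and erythroid genes were below 0 in 8 and below the band in 1, stroma and endothelium markers in 7 and 1, mature T, NK and B cell markers in 6 and 1, and antigen presentation genes in 6 and 1, with 1 above. H3K4 complex genes were above the band in 3, cell cycle genes in 2 and silent tissue genes in 2. HSC identity, lymphoid, NF-kB and IL-1 response, quiescence and immediate early, p53 response and housekeeping genes were outside the band in 0 of 8.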

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

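Of the tests below, those of list length, covered length, window length and Kmt2c copy number were chosen only after the results were seen, although equal numbers of peaks were an alternative fixed beforehand. In addition, 3 pairs of shares drew attention because the same contrast went in opposite directions in 2 groups of mice. The differences between the groups were not tested. In HSC H3K4me1, 77.0% of the strong exclusive regions lay in the knockout list at 8 weeks and 37.5% at 16 weeks after PBS. Strong was set within each list, so the 2 shares rest on unlike thresholds. At 8 weeks 62.4% (knockout) and 57.1% (wild type) of peaks had −log10 q of 5 or more. After PBS the values were 1.04% and 1.01%. In HSC H3K27ac, 24.9% lay in the knockout list after PBS and 55.8% after 5FU. In HSC H3K4me1, 97.8% lay in the 5FU list in wild type and 37.7% in knockout, and the wild-type 5FU list came from 6 libraries of 2 series. In each pair, at least 1 share changed direction with lists of equal covered bases (8.80% and 78.8%, 98.2%, and 0.615%).

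Relative to the median gene, interferon response genes were covered less by H3K4me1 in the knockout lists of HSCs at 8 weeks, of HPCs and of HSCs after PBS and after 5FU. The number of peaks alone was argued against, since the list stayed below the central 95% of random lists in 4 of 4 comparisons with lists limited to equal numbers of peaks, as were short windows of these genes, with 4 of 4 comparisons after matching on window length. A difference in covered length is a candidate explanation in HSCs at 8 weeks and after 5FU. With lists limited to equal covered bases the list was below the band in 1 of 4 comparisons, that of HPCs. The median was then 0.007 in HSCs at 8 weeks and after 5FU, but −0.125 after PBS, against −0.131 in the deposited lists. With 10 kb windows the calls after PBS and after 5FU ended too, with medians of −0.054 and −0.079 (percentiles 21.9 and 23.7). For H3K27ac the limit to equal covered bases lowered the percentiles. In HSCs the percentiles went from 4.58 to 1.01 after PBS and from 1.01 to 0.21 after 5FU. The medians there did not become lower, going from −0.119 to −0.118 and from −0.173 to −0.143. In HPCs the percentiles went from 18.5 to 5.76 after PBS and from 15.95 to 2.23 after IL-1. The medians there went from −0.049 to −0.070 and from −0.063 to −0.085. A graded effect of Kmt2c copy number stayed open: the heterozygous lists were below the band in 0 of 2 comparisons, but 0.5 of the knockout median (−0.07 in HSCs and −0.05 in HPCs) would itself lie inside the band. A lowering of the mark is not shown in HSCs at 8 weeks, where the median before centring was 0.24 in favour of the knockout list.

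Relative to the median gene, granulocyte and monocyte genes were covered less in knockout HSCs in H3K4me1 at 8 weeks (0.18, more in knockout, before centring) and in H3K27ac at 16 weeks after PBS and after 5FU, the 3 of 5 HSC comparisons in which the list stood apart downwards. For fewer HPC-like cells among the sorted knockout HSCs, genes that HPCs cover at least 1.5-fold more than HSCs were examined. They were chosen from the heterozygous H3K4me1 lists at 8 weeks. Their median was −0.02, −0.03 and −0.03 over 1427, 1102 and 1131 genes and reached 0.5 of the median of the list in 0 of 3 comparisons. For H3K4me1 at 8 weeks these genes as a set were thus not lowered as the list was. They were not matched to the list on covered length, in a comparison whose knockout list covered more. They also represent HPCs as a whole, so fewer such cells, or fewer granulocyte and monocyte progenitors alone, cannot be excluded. Genes chosen by H3K4me1 need not gain H3K27ac peaks from HPC-like cells, so for H3K27ac the test cannot decide. The number of peaks alone was argued against by 3 of 3 comparisons below the band with lists limited to equal numbers of peaks, although the percentile after PBS was exactly 2.5, on the edge of the band. A difference in covered length is a candidate explanation for both H3K27ac comparisons, since with lists limited to equal covered bases the list was below the band in 1 of 3, that of H3K4me1 at 8 weeks. Mature T, NK and B cell markers (−0.24) and megakaryocyte and erythroid genes (−0.20) were also lower for H3K27ac after PBS and stroma and endothelium markers (−0.20) after 5FU, so fewer cells of other kinds stayed untested, as did sex, depth and differences between libraries.

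The excess of strong regions exclusive to knockout HSCs at 8 weeks was weighed against the smaller wild-type list. The knockout share was 58.5% with lists of equal numbers of peaks and 8.80% with lists of equal covered bases, so fewer peaks in the wild-type list and an effect of the genotype cannot be told apart for these regions. A wild-type list apart from both other lists stayed open too. Knockout against heterozygous gave 68.5% in knockout (65.6 to 71.2, 715 and 329 regions), above the bound of 60% set before the test for arguing against it. That bound took no account of the longer knockout list, and after the shares of 57.0% with equal numbers of peaks and 33.7% with equal covered bases were seen it was no longer relied on.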

How the results depend on the processing

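Leaving out chromosomes X and Y, matching on window length and limiting lists to equal covered bases were tests chosen after the results were seen. No paired analysis was possible because each list covers all libraries of its group, and for the same reason leave-one-out was not possible. Of 154 values recomputed, 106 lay within the 95% interval of the value reported (for counts, within 1.5 times of it), 33 moved out of it and 15 changed direction, and the cause was not tested except where fewer peaks or regions follow from the setting. With −log10 q of 5 or more, the share in the second list was 83.2% and 76.1% for knockout and heterozygous HSCs at 8 weeks, 23.9% and 34.8% for HPCs, 78.4% for HPCs against HSCs, 100% for H3K27ac in wild-type HSCs under 5FU (2 regions), 41.6% and 100% for H3K4me1 under 5FU in knockout and wild type, and 31.5% and 0.0% for H3K4me1 in knockout HSCs after PBS and 5FU. It changed direction to 11.1% (H3K27ac, knockout HSCs under 5FU, 9 regions), 53.8% (H3K27ac, knockout HSCs after PBS, 13 regions) and 14.8% (the same after 5FU, 27 regions), and the odds ratio between HSCs at 8 weeks and after PBS to 0.6 (7 regions). With lists limited to equal numbers of peaks the shares were 58.5%, 57.5%, 43.3%, 41.7% and 57.2% for the 5 comparisons at 8 weeks in that order, 57.8% and 62.4% for H3K27ac under 5FU in wild type and knockout, 45.5% for H3K27ac in knockout after PBS, 64.5% and 41.4% for H3K4me1 under 5FU, and 43.8% and 19.5% for H3K4me1 in knockout after PBS and 5FU. With lists of equal covered bases the share changed direction to 8.80% and 14.4% for knockout and heterozygous HSCs at 8 weeks, 19.6% for HPCs against HSCs, 30.0% and 0.615% for H3K27ac and H3K4me1 in wild type under 5FU, 98.2% for H3K27ac in knockout HSCs after PBS, and 78.8% and 99.2% for H3K4me1 in knockout after PBS and 5FU, and moved to 61.2% for H3K27ac in knockout under 5FU, 99.8% for H3K27ac in knockout HSCs after 5FU and 100% for H3K27ac in knockout HPCs after IL-1 (9 regions). This setting takes weak peaks only from the list that covered more, so a turn can follow from the setting itself. With an overlap of 50% they were 73.1% and 64.7% for knockout and heterozygous HSCs, 49.8% (changed direction) for HPCs against HSCs, 96.6% for H3K4me1 in wild type under 5FU and 0.886% for knockout after 5FU. With strength by fold enrichment they were 57.4% for knockout HPCs, 49.3% (changed direction) for HPCs against HSCs, 90.3% for H3K27ac in knockout under 5FU, 39.9% (changed direction) for H3K27ac in knockout after 5FU, 45.5% for H3K4me1 in knockout under 5FU and 0.885% for H3K4me1 in knockout after 5FU. Leaving out chromosomes X and Y left 26 of 26 values within those limits, with wide intervals: the odds ratio of H3K27ac in knockout HSCs after PBS and 5FU went from 51.8 to 37.0, that of H3K27ac under 5FU in wild type and knockout from 2.94 to 4.91, and the knockout share after PBS from 24.9% to 21.8%. Of the 45 gene lists apart, 22 remained so with 10 kb windows, 33 with 1 gene per 100 kb, 33 with 5000 added bases, 34 with equal numbers of peaks, 20 with equal covered bases, 41 with matching on window length and 43 without X and Y. No value could be computed with −log10 q of 5 or more for the 4 H3K27ac comparisons of HPCs and 7 of the 10 odds ratios, or with equal covered bases for 4 of them. Read depth is unknown, so weak peaks missing from shallow lists cannot be counted.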

Other observations

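No test in this part was planned, and the genes named here were chosen after their values were seen. Of the 28 interferon response genes, 7 lay below the median gene in all 4 H3K4me1 comparisons of knockout with wild type, among them Gbp2, Gbp3, Ifih1 and Zbp1. Ifih1, a sensor of viral RNA, had relative log2 ratios of −0.19 and −0.34 in HSCs and HPCs at 8 weeks and −0.45 and −0.30 in HSCs after PBS and 5FU, and Gbp3, a guanylate-binding protein, had −0.30, −0.35, −0.24 and −0.44. Bst2, which tethers virus particles to the cell, lay above the median gene in 3 of 4 (0.11, 0.03, 0.43 and −0.20). Irf9 and Stat2 likewise lay below it in only 1 of 4, and Oas1a in 1 of 3. The share of all genes that lie below the median gene in all 4 is not given here, so the 7 of 28 has no reference value.

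Y-linked peaks were found in H3K27ac lists and in 0 of the H3K4me1 lists. In HPCs there were 4 (wild type, PBS), 1 (wild type, IL-1), 0 (knockout, PBS) and 3 (knockout, IL-1), with a best −log10 p by the authors' peak caller of 28.1, 5.27 and 8.96 in the lists that held any.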
